A study of Bacillus subtilis subsp. subtilis and Bacillus spizizenii with 61 samples.

How the data were processed

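Genomic DNA from 19 Bacillus strains was co-hybridised with Bsu168 DNA on arrays made for Bsu168, and Bsu168 was hybridised with itself on 3 arrays. Per the labels' protocols, cultures were grown in LB medium to mid or late log phase, and the DNA was cut with Sau3AI and labelled with Cy3 or Cy5 dCTP. The strain was in Cy5 on 21 arrays and in Cy3 on 37, and 17 strains had both orientations. W23 and HIKEM-7 had the strain in Cy3 on every array.

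The deposited values were log2 ratios, 1 per probe and array, in a value table of 3722 probes and 61 arrays. Their scale was read from the range, with a lowest value of -17.23. Each array's deposited log2 median lay within 0.000835 of 0, so the values appear to have been centred on the median before they were deposited. The scanner, background correction, spot filter and normalisation are not given in the sources used here. Empty cells made up 1.57% of the table, and 92 values were below -10. No columns held identical values.

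The direction is not stated either. Arrays of 1 strain with opposite dyes correlated positively across probes in 35 of 36 pairs (median r 0.769, lowest -0.025), and arrays with the same dyes in 24 of 24 (median r 0.753). The values were therefore read as deposited in a fixed direction, and no array was turned. Strain over Bsu168 was taken as the likely direction because the eps::tet mutant had a run of strongly negative probes. The lowest correlation between arrays of different strains with the same orientation was -0.268.

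None of the 3722 probe identifiers matched the 4536 genes of the reference table, of assembly ASM904v1, and no gene was named from a probe number. The 33 gene lists, centring on ribosomal protein genes and removal of an origin to terminus trend were planned and not run for this reason. Probes were put in the order of their numbers, from 1 to 4107. Their order on the chromosome is not given in the sources used here. The rule for named genes, fixed before the data were examined, ranked called genes by the number of isolates or by size within each comparison. It would have named up to 15 per direction, and was shortened to the first 2 per direction of each comparison because probes have no gene names. The single lowest probes of other isolates were left out.

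Arrays were centred on their median. For each strain, limma (version 3.58.1, R 4.3.3) was fitted to all 61 arrays with a mean per group, so that all groups shared an estimate of the spread, and the strain was compared with the self arrays. A probe needed values on at least 2 arrays of the strain and 2 self arrays. It was called lower or higher at a Benjamini-Hochberg adjusted p under 0.05 within the strain and a ratio of at least 2-fold. Spizizenii and subtilis isolates were compared with limma on strain means, so that the isolate was the replicate, with at least 5 and 7 isolates measured. Numbers of lower probes and the similarity of isolates were compared by exact permutation over all 19448 splits of the 17 isolates, two-sided. Runs were at least 5 called probes with at most 1 uncalled probe between neighbours, and calls were shuffled 1000 times for comparison. Merging of overlapping runs into regions was added later. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

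The fits were tested on simulated data with 50 probes changed at each size. For natto against self, 98% of probes changed by -3 and 80% of those changed by -1.5 were called, with 84% at 1.5 and 94% at 3, and 5 unchanged probes of 3710 tested were called. For spizizenii minus subtilis the shares were 100%, 82%, 90% and 98%, with 3 unchanged probes called of 3706. The simulated noise was normal with 1 spread per probe in all groups, as the fits assume. Real values reached -17.23 and groups need not share a spread, so these shares may not hold for the real arrays.

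Alternatives were no centring, centring on the mode, only the 1912 probes with values on all 61 arrays, a dye term, a limit of 1.5-fold, the replicate number as a block, tests against 0, self arrays with the sign turned, only the strain's and self arrays in the fit, and leaving out each array or isolate. Flooring values at -6, leaving out each self array and leaving out the doubted BS5 replicate 1 were chosen after seeing the data. Ratios of this kind fall where a strain lacks a sequence and also where its sequence differs from the probe, and the 2 cannot be separated from these values. Sequences that Bsu168 lacks are not measured.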

Results

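Genomic DNA of 19 strains was compared with that of Bsu168, the laboratory strain of Bacillus subtilis whose genome the arrays were designed on, by hybridisation of both DNAs to 1 array in different dyes. The strains were 10 isolates of subspecies subtilis, 7 isolates of subspecies spizizenii, 1 isolate of the close relative Bacillus vallismortis and a Bsu168 derivative with a tetracycline marker in the eps locus, which directs exopolysaccharide synthesis in biofilms. Each strain had 3 arrays except the spizizenii isolate N10, with 4, and Bsu168 was hybridised against itself on 3 arrays. The 61 arrays held between 3147 and 3719 measured probes of 3722. A log2 ratio below 0 is taken as less signal from the strain than from Bsu168. This direction is likely rather than stated, and rests on the correlation of arrays with opposite dyes and on the mutant. Log2 ratios of strains, probes and regions are given minus the mean of the self arrays. Values per array, tests against 0, correlations and scores at probes chosen without an isolate do not have the self arrays taken off. The number of arrays limits the precision. The labels do not say that the arrays of a strain came from separate cultures, so the spread between them may be technical. In the main fit, p-values and SEs of a strain use this spread pooled over all groups. They do not measure the spread of the strain's own arrays alone. Probes are given by their numbers because no table used here pairs them with genes.

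The eps::tet mutant was used to set the direction, so its lower probes are no separate check of it. No probe was matched to an eps gene, so the place of these probes was not checked against the label. On its arrays 14 probes were lower than on the self hybridisations, and these 14 had consecutive numbers, from 3691 to 3704. Their median log2 ratio was -2.75 relative to the self arrays, on which the same probes had a median of -0.03 as centred. The median over these probes was -1.27, -4.37 and -3.39 on the 3 mutant arrays (SD 1.58, n = 3). Relative to the self arrays, BSO2-3695 had a mean log2 ratio of -7.85 ± 1.46 (SE, n = 3; limma adjusted p = 0.000942) and BSO2-3691 one of -4.97 ± 0.69 (SE, n = 3; limma adjusted p = 4.28e-06). The first rests on a value of -16.79 on replicate 2, with -1.22 and -5.50 on replicates 1 and 3, and values this low may not be exact measurements. With values under -6 set to -6, a setting chosen after seeing the data, the means were -4.25 and -4.27, so their order turned, and both stayed called. One further probe, BSO2-1240, was higher at 1.17 ± 0.26 (SE, n = 3; limma adjusted p = 0.013), and that call was lost without mutant replicate 3 or without self replicate 1 or 3, each leaving 0 higher probes. None of the 14 probes was lower in any of the 18 isolates. The calls rest on a spread pooled over all strains: with limma fitted to the mutant and self arrays alone, the adjusted p was 0.997 for BSO2-3695 and 0.979 for BSO2-3691, and neither was called.

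**Figure D1:**
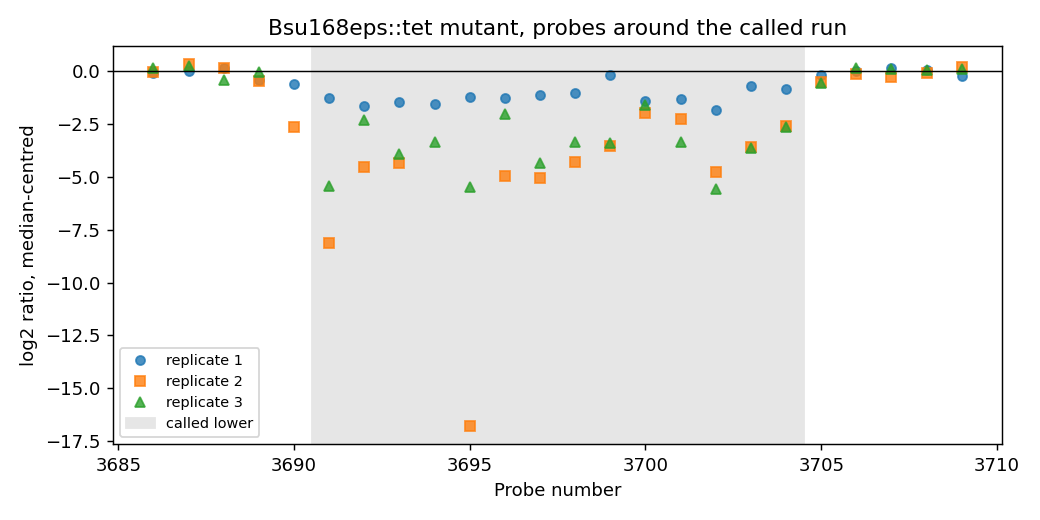
Median-centred log2 ratio of each mutant array against probe number, with a symbol per replicate and the called run shaded. The 14 shaded probes run from 3691 to 3704, replicate 1 lies nearest to 0 over them with a median of -1.27, and probe 3690 beside them is also below 0 without being called.

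The series asked how far the genomes of the species' members differ. Within subspecies subtilis the number of probes lower than in Bsu168 ranged from 0 in NCIB3610 to 209 in natto, a strain used to ferment soybeans. BS5 had 17 lower probes, RO-NN-1 30, HIKEM-7 53, 1431 72, MGla47 103, HLR11 127, 1440 135 and T-89-48 157. Higher probes were fewer than lower ones in 8 of these isolates, with at most 22, in 1431, while BS5 had 72. For NCIB3610, limma called 0 probes in either direction. Of 3715 tested probes 166 had an unadjusted p under 0.05, which is below the share of 0.05 that chance alone gives. The spread in this limma fit was pooled over all strains and can hide small shifts, so this does not show that NCIB3610 is unchanged. A total of 418 probes were lower in at least 1 subtilis isolate and 0 in all 10. BSO2-2928 was lower in 9 of the 10, with a mean log2 ratio of -3.51 ± 1.61 (SD, n = 10), and BSO2-2920 in 8, at -4.60 ± 2.02 (SD, n = 10). The probes most often higher were BSO2-2425, in 6 isolates at 0.95 ± 0.29 (SD, n = 10), and BSO2-325, in 5 at 1.06 ± 0.40 (SD, n = 10). These higher calls depended on the self arrays: in tests against 0, BSO2-2425 was called in 0 subtilis isolates and BSO2-325 in 1, and with the sign of the self arrays turned both were called in 0.

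Single arrays decided several of these counts. RO-NN-1 had 2, 136 and 3 lower probes without its replicates 1, 2 and 3, and 4, 1 and 7 without self replicates 1, 2 and 3. Without BS5 replicate 1, which lacked 468 values, BS5 had 21 higher probes in place of 72. It had 139 without replicate 2, 182 without replicate 3 and 17 without self replicate 3, and its lower probes fell to 8, 11 and 7 without self replicates 1, 2 and 3. The lower count of 1440 was 40 without its replicate 1 and 68 without replicate 2, and that of 1431 was 9 without its replicate 1 and 40, 41 and 38 without self replicates 1, 2 and 3. HIKEM-7 had 82 lower probes without its replicate 1, 26 without replicate 2 and 33 and 30 without self replicates 1 and 2. MGla47 had 68 without its replicate 2 and 57 and 64 without self replicates 1 and 2. The count was 128 in natto without replicate 2, and 91 and 71 in T-89-48 without replicates 1 and 2. The 22 higher probes of 1431 became 1, 96 and 47 without its replicates 1, 2 and 3, and 6 without self replicate 3.

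**Figure D2:**
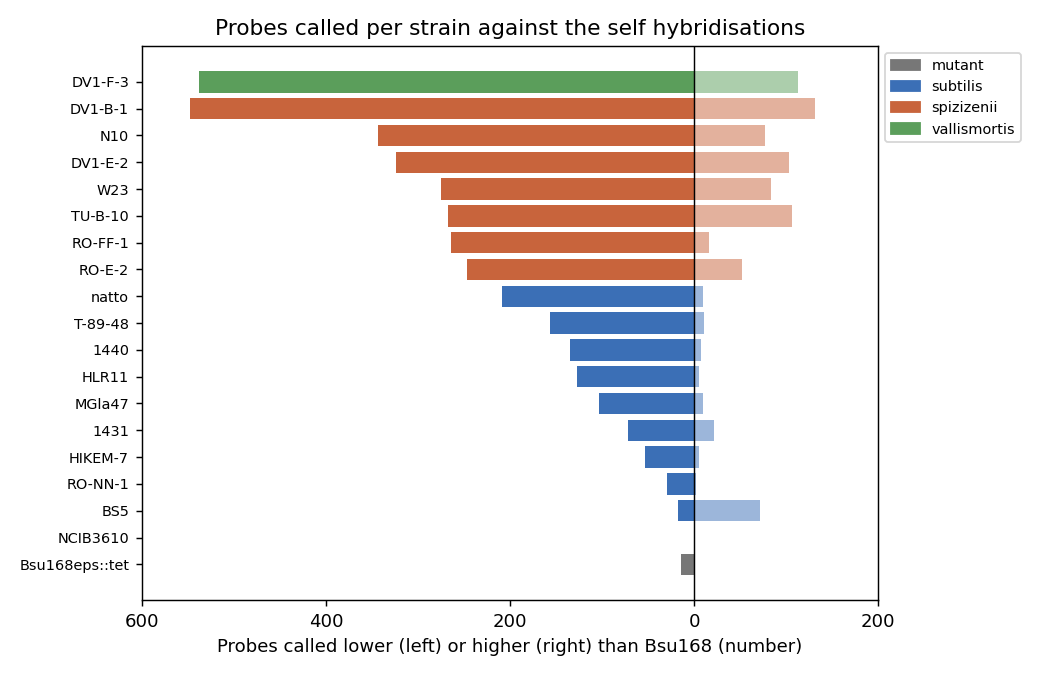
Number of probes called lower (left, full colour) or higher (right, pale) than Bsu168 for each strain, coloured by taxon. NCIB3610 has 0 calls, the other subtilis isolates have 17 to 209 lower probes, and the spizizenii isolates have 247 to 548.

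The 7 spizizenii isolates had more lower probes than the 10 subtilis isolates. Their counts were 247 in RO-E-2, 264 in RO-FF-1, 267 in TU-B-10, 275 in W23, 324 in DV1-E-2, 343 in N10 and 548 in DV1-B-1, a mean of 324 ± 105 (SD, n = 7) against 90.3 ± 67.4 (SD, n = 10). The difference of 233.7 probes passed a two-sided exact permutation test over 19448 splits (p = 5.14e-05, the smallest these splits can give; Benjamini-Hochberg adjusted over 2 measures, 0.000103). The test takes the isolates as independent, although 1440 with 1431 (r = 0.925), HIKEM-7 with HLR11 (r = 0.884) and RO-E-2 with W23 (r = 0.846) were much alike. Since the arrays were made for Bsu168, such counts measure distance from that strain. Every spizizenii isolate lay above the highest subtilis isolate in the fit to all arrays. This separation was lost with only each isolate's own and self arrays in the fit, where natto had 321 lower probes and RO-FF-1 204, while the difference in means still passed (exact permutation p = 0.000154). Higher probes also differed, with 81.1 ± 38.1 (SD, n = 7) against 14.4 ± 21.1 (SD, n = 10; exact permutation p = 0.00072), from 16 in RO-FF-1 (7 without its replicate 3 and 7 without self replicate 3) to 131 in DV1-B-1 (81 with arrays centred on the mode). Without self replicate 3 the mean higher counts were 52.6 and 4.6, and their difference still passed (exact permutation p = 0.000154). The median-centred arrays of spizizenii isolates were also wider, with a median spread of 0.555 (scaled median absolute deviation, 22 arrays) against 0.345 (30 arrays) for subtilis and 0.163 for the 3 self arrays. Without 1 array, the lower count fell to 109 in RO-E-2 (replicate 2), 176 in W23 (replicate 3) and 168 in TU-B-10 (replicate 1), and RO-FF-1 had 191 without its replicate 3 and RO-E-2 190 without its replicate 3, all below the 209 of natto on all arrays. Without self replicate 1, 2 or 3, natto had 168, 174 and 184, and the lowest spizizenii count, in RO-E-2, was 181, 195 and 200.

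In the spizizenii isolates 842 probes were lower in at least 1 and 42 in all 7. Of these 42, 35 were also lower in the vallismortis isolate, and only 5 were lower in no subtilis isolate. All 7 comparisons share the self arrays, so part of the overlap may come from them. Unchanged strains simulated against the same self arrays shared 0 probes in each of 20 simulations. Those strains had no true differences, so this cannot show how much the self arrays add among strains with many calls. Independent lists of these sizes would share 0.000119. Tests against 0, which do not take off the self arrays, gave 90 shared probes. Their spread is still pooled over all groups, self arrays included, and their SEs are smaller. The 90 therefore cannot show how much of the 42 comes from the self arrays. The lowest means among probes lower in all 7 belonged to BSO2-2920, at -5.22 ± 0.70 (SD, n = 7), and BSO2-3419, at -4.86 ± 0.79 (SD, n = 7). BSO2-3419 was lower in 1 subtilis isolate.

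Tested directly on strain means, 143 of 3706 probes were lower and 6 higher in spizizenii than in subtilis isolates (limma, adjusted p under 0.05 and at least 2-fold), and 16 of the 143 differed by at least 8-fold. For 17 of the 143, every spizizenii isolate lay below every subtilis isolate. Chance gives 0.00514% for an unselected probe, which is no baseline here, since the 143 were chosen for being lower in these same isolates. The count over all 3706 probes was not made. BSO2-3408 had the largest difference, -5.53 ± 0.83 (SE; limma adjusted p = 0.000461), with means of -6.08 ± 1.89 (SD, n = 7) and -0.55 ± 1.74 (SD, n = 10). BSO2-3241 followed at -4.42 ± 0.69 (SE; limma adjusted p = 0.000598). With values under -6 set to -6 the differences were -4.47 and -3.67. The largest positive differences were 1.21 ± 0.26 (SE; limma adjusted p = 0.00525) for BSO2-2255 and 1.21 ± 0.21 (SE; limma adjusted p = 0.00111) for BSO2-2166, each called higher in 3 of the 7 isolates. Without RO-FF-1 the test called 177 lower and 18 higher probes, of which 138 and 6 were shared with the test on all isolates.

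The vallismortis isolate, DV1-F-3, had 538 lower and 113 higher probes of 3718. With 1 isolate, its taxon was not tested against the others. Of its lower probes 394 were lower in at least 1 spizizenii isolate, against 123 for independent lists, and 128 were lower in no other isolate. The simulations of unchanged strains gave 0, which cannot show how much the self arrays add among strains with many calls. Part of this overlap may come from the shared self arrays. Tests against 0 gave 461, but with smaller SEs, so the 2 counts cannot be set against each other directly. Relative to the self arrays, BSO2-2926 had a log2 ratio of -7.88 ± 2.49 (SE, n = 3; limma adjusted p = 0.0204) and BSO2-3235 one of -7.22 ± 1.44 (SE, n = 3; limma adjusted p = 0.000147). These sizes rest on very low values, which may not be exact, and with values under -6 set to -6 they were -4.45 and -3.66, both still called. Neither was called with only the isolate's own and self arrays in the fit. BSO2-3920 was the highest, at 2.41 ± 0.55 (SE, n = 3; limma adjusted p = 0.000801), and BSO2-2255 was higher at 1.78 ± 0.42 (SE, n = 3; limma adjusted p = 0.00119). Centred on the mode, which lies up to 0.295 from the median on these arrays, the isolate had 622 lower and 45 higher probes. Its higher probes numbered 177 without its replicate 2, 74 in tests against 0 and 55 with the sign of the self arrays turned, so part of these calls depended on the self arrays.

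Across all 18 isolates 3578 probes were tested in every one, and 2565 of them (71.7%) were lower in none. A further 351 were lower in 1 isolate, 0 were lower in all 18, and 1058 of all probes were lower in at least 1. The highest single ratios belonged to BSO2-2813 in DV1-B-1, at 2.58 ± 0.96 (SE, n = 3; limma adjusted p = 0.0374), and BSO2-1622 in TU-B-10, at 2.56 ± 0.64 (SE; limma adjusted p = 0.00466). The first of these had an adjusted p of 0.0554 with limma when arrays were centred on their mode.

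Part of the lower probes lay in runs of neighbouring numbers, for example 196 of 548 in DV1-B-1, 146 of 343 in N10, 49 of 275 in W23, 7 of 72 in 1431 and 5 of 53 in HIKEM-7. RO-NN-1, BS5 and NCIB3610 had no run. Runs of at least 5 called probes, with 1 uncalled probe allowed between called ones, numbered 26 in DV1-B-1, 17 in DV1-F-3 and 14 in N10, where shuffled calls gave means of 2.23, 2.00 and 0.276. Natto had 7 runs and 1440 had 6, with shuffled means of 0.029 and 0.003. No isolate had a run of higher probes. Overlapping runs merged into 37 regions, of which 15 had a run in 1 isolate. Probes 3407 to 3413 formed a run in all 7 spizizenii isolates and in DV1-F-3, with a mean log2 ratio of -3.33 ± 0.49 (SD, n = 7) against -0.38 ± 1.02 (SD, n = 10) in subtilis isolates, and all 7 probes passed the test between the subspecies. Natto and RO-NN-1 also had low means there, -2.60 and -1.96, without a called run. Probes 3235 to 3243 averaged -2.29 ± 0.52 (SD, n = 7) in spizizenii, -4.44 in DV1-F-3 and 0.08 ± 0.42 (SD, n = 10) in subtilis isolates, and 7 of its 9 probes passed the same test. All 6 probes from 963 to 968 passed it, at -1.43 ± 1.17 (SD, n = 7) and 0.08 ± 0.44 (SD, n = 10), but RO-FF-1 (0.33) and DV1-E-2 (0.08) were not low there, with 0 of 6 probes called in each, and DV1-F-3 stood at -0.20.

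Other regions were low in isolates of both subspecies. Probes 3037 to 3086 held a run in 9 isolates, and 45 of the 50 probes were lower in N10 and 45 in RO-FF-1, which need not be the same probes. The means of these isolates were -3.01 and -3.54. BS5, at 0.41, and DV1-B-1, at 0.12, had no run there. Probes 1772 to 1825 held a run in 11 isolates, with means of -1.29 ± 0.24 (SD, n = 7) in spizizenii and -0.64 ± 0.46 (SD, n = 10) in subtilis isolates. The 53 measured probes from 2758 to 2923 averaged -2.95 ± 0.52 (SD, n = 7) and -2.50 ± 1.16 (SD, n = 10), and 0 of them passed limma's test between the subspecies, which called 143 lower probes elsewhere and had 1206 probes at an unadjusted p under 0.05 over the array. Probes 2253 to 2262 formed a run in natto alone, whereas the spizizenii mean there was 0.27 ± 0.22 (SD, n = 7). A region without a run in an isolate is not shown to be unchanged, since wide spread or few values can end a call.

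**Figure D3:**
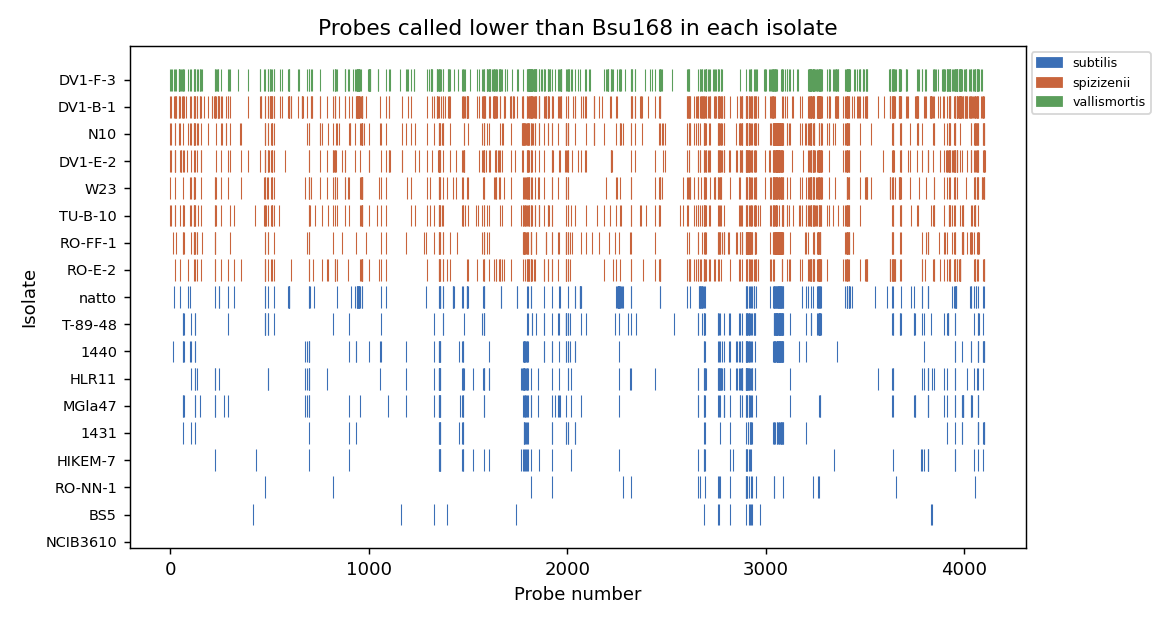
Each line marks a probe called lower than Bsu168, by probe number (horizontal axis) and isolate (vertical axis), coloured by taxon. Blocks of lines such as 3407 to 3413 in the 7 spizizenii isolates and 3037 to 3086 in isolates of both subspecies are the runs described in the text.

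The isolates' mean log2 ratios were correlated across probes, which are not independent replicates. The mean r was 0.439 over 45 pairs of subtilis isolates, 0.663 over 21 pairs of spizizenii isolates and 0.45 over 70 pairs between the subspecies. The mean within-subspecies r exceeded the between-subspecies mean by 0.0607, which did not pass a two-sided exact permutation test (p = 0.0637). This call depended on the measure: with each probe centred on its mean over the 17 isolates the difference was 0.330 (exact permutation p = 5.14e-05), and with Spearman correlations 0.0835 (p = 0.0151 by the same exact test). It depended on single isolates too. Without any 1 of the 10 subtilis isolates the difference passed the exact permutation test, from 0.0597 without HIKEM-7 (p = 0.0362) to 0.0944 without NCIB3610 (p = 0.000962). Without any 1 of the 7 spizizenii isolates it did not pass, and it was lowest without DV1-B-1, at 0.0338 (exact permutation p = 0.64). The closest pairs were 1440 with 1431 (r = 0.925), HIKEM-7 with HLR11 (r = 0.884) and RO-E-2 with W23 (r = 0.846). RO-FF-1 was closest to RO-NN-1, of the other subspecies (r = 0.744). DV1-F-3 had a mean r of 0.55 with spizizenii and 0.296 with subtilis isolates.

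**Figure D4:**
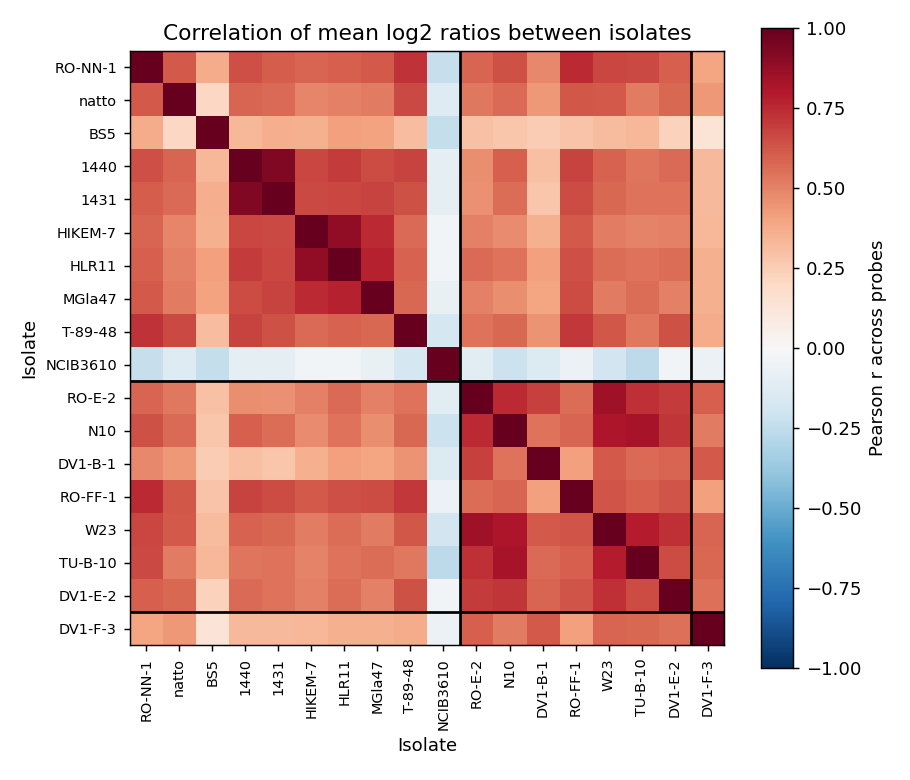
Pearson r across probes between the mean log2 ratios of the isolates, from -1 to 1, with lines between the taxa. Spizizenii isolates correlate with each other at a mean of 0.663, and NCIB3610 correlates below 0 with every other isolate.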

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

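The test of compressed ratios in RO-FF-1 was chosen only after its values had been seen and is the last of 3 tried, and the floor of -6 and the counts without a self array were also chosen after seeing results. Of 25 groups of values examined, 6 had 1 sample far from the others. The limit used is meant to flag about 1 in 20 groups of normally distributed values, and its rate by chance for these values was not tested.

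The 7 spizizenii isolates differed from the 10 subtilis isolates at 143 lower and 6 higher probes, and by 233.7 lower probes per isolate, each by a test of the difference itself. Of 100 splits of the 17 isolates, the real split included, 1 called as many probes as the real 149. The highest of the others called 8. This argues against chance for this grouping, with the isolates taken as independent although some pairs were much alike. For N10, 1 of 35 splits of the 7 arrays, the real one, reached 420 calls, a share under 0.05 and the smallest these splits can give. All 19 strains were split in this way without correction, so this does not exclude chance for N10. The highest other split called 375 and placed the 3 self arrays together in the larger group, which nearly exchanges the groups. For the 18 strains with 3 arrays the 10 splits are too few for a share under 0.05. The real split called the most in 17 of these, as 1 split of 10, and the highest of the other splits called from 0 to 134 probes. The 134 belonged to DV1-F-3, which had 651 in the real split, RO-NN-1 had 22 against 32, and the mutant 8 against 15. In NCIB3610 all 10 splits called 0.

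Higher probes in spizizenii isolates form the first pattern, with a mean of 81.1 per isolate. It was 52.6 without self replicate 3 and 66.4 in tests against 0, which do not take off the self arrays. Centring on the mode left 58.1 and a dye term 84.3, both above 40.6, so neither accounts for the whole pattern, although the mode removed part of it. In tests against 0, 301 probes were higher in at least 1 of the 7 isolates, 17 in at least 4 and 0 in all 7. Shuffled lists had at most 1 probe higher in at least 4, over 1000 shuffles. For those 17 probes this argues against noise that differs from array to array, and it does not decide the question for the others. Probe effects shared by all spizizenii arrays and extra copies in this subspecies, a biological explanation, both stay open and were not tested.

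RO-FF-1 forms the second pattern: it has the fewest higher probes of its subspecies, and its mean r was 0.555 with subtilis isolates, where the other 6 spizizenii isolates had 0.322 to 0.478. With the other spizizenii isolates its mean r was slightly higher, at 0.567. DV1-B-1 also had 0.567 there, and W23 had the highest value, 0.736. Ratios compressed by 1 factor over its whole arrays are argued against: with values floored at -6, in 9 regions with a run in at least 4 of the other 6, it was the lowest of all 7 in 2, with -3.39 ± 0.91 (SD, n = 3) at probes 2758 to 2923 (others -3.09 to -2.29), yet had 0.04 ± 0.17 (SD, n = 3) at probes 3922 to 3930 (others -1.58 to -0.93). At 73 probes lower in all of the other 6 its floored mean of -2.12 was nearer to 0 than theirs at probes chosen in the same way (nearest -2.61), so a compression of part of its ratios stays open. A taxon label that belongs to a subtilis isolate cannot be told apart from a real difference within spizizenii, which was not tested: with each isolate scored at probes chosen without it, its mean of -0.857 lies next to RO-NN-1 (-0.827) and natto (-0.809), the lowest subtilis isolates, and far from the nearest spizizenii isolate (-1.87). Other values go with the label as given: 264 lower probes against at most 209 in subtilis isolates (204 against 321 with own and self arrays only), and 7 of 7 probes called from 3407 to 3413, at -3.99, where natto, the lowest subtilis isolate, had 3 of 7 at -2.60.

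DV1-B-1 had 548 lower probes, with the next spizizenii isolate at 343, and BS5 had 72 higher probes, with the next subtilis isolate at 22. The count of BS5 was 1 with only its own and self arrays in the fit, 34 with the self arrays turned, 30 on probes with all 61 values and 117 with arrays centred on the mode. It was 21 without its replicate 1 and 17 without self replicate 3. At probes 963 to 968 natto had a mean log2 ratio of -1.06, with the next subtilis isolate at -0.0907. At probes 2665 to 2697 it had -1.77, with the next at -0.439. At probes 1351 to 1359 DV1-B-1 had -0.314, with the next spizizenii isolate at -2.28. At probes 2758 to 2923 NCIB3610 had 0.512 relative to the self arrays, with the next subtilis isolate at -1.96.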

How the results depend on the processing

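Flooring values at -6 and leaving out a self array, BS5 replicate 1 or, for the similarity, an isolate were chosen after seeing the data. Centring on ribosomal protein genes, removal of an origin to terminus trend and the gene lists were not run, since probes have no gene names. No centring, centring on the mode, a dye term and a limit of 1.5-fold left the lower counts of all 19 strains within 1.5 times. So did the replicate number as a block, which moved the difference in lower probes per isolate from 233.7 to 240.03 and raised the higher probes of N10 from 77 to 139. Over 190 pairs each, arrays with the same number had a median r near 0 (0.0076, 0.00544 and 0.035 for numbers 1, 2 and 3). Of these pairs 26.8%, 22.1% and 34.2% had an r over 0.1. The medians show no pairing of all arrays by number, but cannot exclude a batch shared by some of them. The difference in lower probes per isolate passed its exact permutation test under each alternative run. Only probes with all 61 values, 51.4% of probes and 48.7% of the lower ones, gave fewer calls by construction: lower counts were 4 in RO-NN-1, 102 in natto, 2 in BS5, 51 in 1440, 24 in 1431, 30 in HIKEM-7, 58 in HLR11, 109 in RO-E-2, 154 in N10, 282 in DV1-B-1, 108 in RO-FF-1, 56 in MGla47, 278 in DV1-F-3, 123 in W23, 133 in TU-B-10, 58 in T-89-48, 149 in DV1-E-2 and 6 in the mutant. On those probes 72 were lower between the subspecies, 14 lower in all 7 spizizenii isolates and 515 in at least 1 isolate, with mean higher counts of 6.9 (subtilis) and 35.571 (spizizenii). For the changes that follow, the cause was not tested. In tests against 0, lower counts were 174 in RO-NN-1, 55 in BS5, 158 in 1431, 143 in HIKEM-7 and 189 in MGla47, and 90 probes were lower in all 7 spizizenii isolates. With the self arrays turned, RO-NN-1 had 61, and mean higher counts were 5.8 (subtilis) and 52.143 (spizizenii). With the strain's own and self arrays alone, lower counts were 321 in natto, 9 in BS5, 38 in 1431, 130 in HIKEM-7, 173 in MGla47 and 0 in the mutant, and the mean higher count in subtilis isolates was 6.4. With values floored at -6, they were 63 in RO-NN-1, 28 in BS5 and 88 in HIKEM-7. A limit of 1.5-fold gave mean higher counts of 23.7 (subtilis) and 218 (spizizenii), and 228 lower and 69 higher probes between the subspecies. The similarity difference of 0.0607 passed its test at 0.083523 with Spearman correlations, 0.076057 over probes lower in at least 1 isolate and 0.32979 with probes centred on their means, and ranged from 0.033785 to 0.094431 without 1 isolate. Single named probes were refitted under the alternatives that leave out no single array or isolate, the fit to own and self arrays only included. Of these comparisons 142 kept the call or the number of isolates within 1.5 times. In 11 the call was lost or was made in fewer isolates. Single named probes were not refitted without 1 array.

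Without 1 array of the strain or 1 self array, lower counts ranged from 1 to 136 in RO-NN-1, 128 to 193 in natto, 7 to 25 in BS5, 40 to 162 in 1440, 9 to 93 in 1431, 26 to 82 in HIKEM-7, 91 to 123 in HLR11, 109 to 279 in RO-E-2, 268 to 363 in N10, 465 to 562 in DV1-B-1, 191 to 280 in RO-FF-1, 57 to 89 in MGla47, 424 to 586 in DV1-F-3, 176 to 266 in W23, 168 to 245 in TU-B-10, 71 to 184 in T-89-48, 218 to 329 in DV1-E-2 and 11 to 13 in the mutant. NCIB3610 had 0 with limma throughout. On all its arrays 166 of 3715 probes had an unadjusted p under 0.05 with limma. That is no more than chance alone gives, but the spread pooled over all strains can hide small shifts. Without 1 isolate, 116 (without DV1-B-1) to 177 (without RO-FF-1) probes were lower between the subspecies. From 5 (without 1440, RO-E-2, W23 or TU-B-10) to 18 (without RO-FF-1) were higher. Without 1 self array the mean higher counts ranged from 4.6 to 15.8 (subtilis) and 52.571 to 89.429 (spizizenii), both lowest without self replicate 3. The difference in lower probes per isolate, without 1 isolate, ranged from 196.37 to 246.89. Low signal and missing values limit what can be called, and signal over background is not given in the sources used here.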

Other observations

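All comparisons in this part were chosen after the overall slope of NCIB3610 or the mean of its probes 2758 to 2923 had been seen. Those probes, low in most isolates, had positive mean log2 ratios on 2 of the 3 NCIB3610 arrays: 0.497 on replicate 2, with 50 of 53 probes above 0, and 0.756 on replicate 3, with 53 of 53. Replicate 1 had -0.0586, with 17 of 43 measured probes above 0. The self arrays had 0.0763, -0.0169 and -0.279, and the mutant 0.044, 0.0774 and -0.0682. With limma, 0 of these probes reached an unadjusted p under 0.05 in NCIB3610. The spread pooled over all strains can be large here, as for BSO2-2920, at 0.67 ± 1.23 (SE) in NCIB3610. The test therefore cannot show that these probes are unshifted.

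A trend of NCIB3610 along the probe numbers was the third pattern weighed. The slope of the log2 ratio on the distance from the middle of the numbering had a mean of -0.22, from -0.3 ± 0.269 (SE) on replicate 2 and -0.368 ± 0.288 (SE) on replicate 3, while replicate 1 had 0.00836 ± 0.0527 (SE). No slope of these 3 arrays exceeded its SE by much, and such slopes were not particular to NCIB3610: DV1-E-2 had -0.306, -0.211 and -0.336 and DV1-B-1 -0.273, -0.3 and -0.164 on their 3 arrays. A copy number gradient from the middle to both ends, which growing cultures could show, was argued against: the slopes below and above the middle had the same sign on 0 of the 3 arrays. On replicate 2 they were 0.608 ± 0.172 (SE) below and -1.34 ± 0.547 (SE) above, and opposite signs recurred in other isolates. Many of the steepest were on arrays numbered replicate 3: 1.66 and -2.03 in DV1-F-3, 1.22 and -1.52 in RO-FF-1, 0.885 and -1.06 in HIKEM-7. Other replicate 3 arrays lacked them, such as T-89-48 (0.0348 and 0.0227) and BS5 (-0.223 and 0.263), and DV1-B-1 had 0.781 and -1.2 on replicate 1. A spot layout shared by all arrays was argued against too, since the self arrays had slopes of -0.0399, 0.0121 and 0.0462, so that 0 of 3 came near the mean of NCIB3610. A pattern shared by arrays with the same replicate number was not tested for these slopes and stays open. Probe numbers are not known to follow the chromosome, and the source of the trend stays open.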
